A study of Mus musculus with 16 samples.

How the data were processed

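RNA from 16 MMTV-Neu mammary tumours, labelled with the mouse strain FvB, was measured on an Illumina mouse bead array, with 1 array per tumour. MMTV-Neu mice express the Neu oncogene from a mouse mammary tumour virus promoter and develop mammary tumours. Per the labels, 5 tumours were primary, 2 were secondary tumours grown after transplantation of lineage-negative (lin-) cells and 9 were secondary tumours grown from a single tumour-initiating cell (TIC). Per the labels, every tumour was below 1 cm in diameter, total RNA was extracted with Trizol and checked on a Bioanalyser, and the label was biotin. The names of primary tumours start with N and those of secondary tumours with WT, and the labels do not state the genotype of the hosts, so a difference between hosts cannot be told apart from that between primary and secondary tumours. The labels do not say whether tumours shared donor animals or cell preparations, so the p-values measure the spread between these tumours.

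The deposited table of non-normalized values holds, per the file headers, an intensity on a linear scale for each of 25697 probes in each tumour. Per the file headers, the same deposited table gives a detection p-value beside each intensity. The authors' processed table holds quantile-normalized intensities on a linear scale, as judged from its values, because its columns shared their quantiles and each column had a rank correlation of 1 with the non-normalized column of the same tumour. Median processed intensity ranged from 151.8 to 152.1 between arrays. BeadStudio was used, per the submitters' processing notes. Its version and the background steps inside it are not given in the sources used here, and no genome build is given. Groups were taken from the sample labels and all 16 columns were matched to a tumour by name.

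Probe names came from the array annotation supplied with the data. It gave 1 gene symbol for 23978 probes, several for 0 and none for 1719. The symbols of 23962 probes were looked up by Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, used for names only, and 0 changed. Genes without a named probe were not analysed here. Among them were Erbb2, the mouse gene of the Neu oncogene, Mki67 of the proliferation list and Epcam of the luminal list.

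The main values were made from the non-normalized intensities with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with the negative-control distribution inferred from the detection p-values (function nec, offset 16), followed by quantile normalization and log2 transformation. Fold changes are therefore on the scale of log2 normalized intensity with that offset, which understates changes of dim genes. A probe was kept when its detection p was under 0.05 on at least 2 arrays, which left 14520 probes, 13681 of them named. Each of the 9903 genes tested was represented by its kept probe with the highest mean over all arrays. Named genes whose kept probes differed in direction are marked where they appear.

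Groups were compared with lmFit and eBayes in a fit with 3 group means, so that the comparisons shared 1 estimate of the spread, which the lin- group of 2 tumours needed. All secondary tumours were compared with primary tumours in a fit with 2 means. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Adjusted p-values of genes are limma's. Gene lists for cell types, pathways and transplant-related markers were fixed beforehand, and 25 of 26 lists had at least 5 measured genes (the skin keratinocyte list did not). Lists were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, and adjusted over the lists. The same lists were run through camera with an estimated correlation. They were also run through fry, which asks whether the genes of a list move, on balance, in 1 direction and does not compare them with other genes. List scores are the mean over list genes of log2 intensity minus the gene's mean over all tumours. Scores were compared by exact permutation of tumours between groups, a test chosen after the data were seen. A gene's member count is also given adjusted over the list alone.

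The genes to be named were chosen by rule. Among genes with an adjusted p under 0.05 for which every tumour of the first group lay on the same side of the mean of the second group, the 12 largest rises and 12 largest falls were taken for single TIC against primary, and 6 and 6 for the other comparisons. The rule added up to 4 members of each list with the largest absolute change, whether or not they passed, and a few surface markers. Genes named outside the rule are said to have been chosen after their values were seen. Where no array of a group detected a gene, its change is given as a lower bound. The bound sets the mean of the brighter group against the mean, over the arrays of the dim group, of the higher of the gene's own value and the lowest value of any detected probe.

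Similarity between tumours was measured by Pearson r over the 9903 genes, and compared within and between the primary and single TIC groups over all 2002 splits of the 14 tumours into 5 and 9. Spread within groups was compared by Euclidean distance after centring on group means and scaling by group size. Clustering used average linkage on 1 minus r over the 1000 most variable genes. The tests were run on simulated data with 200 genes changed by known amounts among 9903. For single TIC against primary tumours, 37.3%, 74.6% and 95.5% of genes changed by 0.5, 1 and 2 log2 units were recovered. The shares were 4.48%, 50.7% and 92.4% for lin- against primary tumours and 20.9%, 61.2% and 86.4% for single TIC against lin- tumours. The simulated noise was independent between genes and the number of changed genes was set, so these shares are not the power of the real comparisons. Figures were drawn with Python 3.11.15.

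The groups, tests, lists, naming rule and a set of alternatives were fixed before the data were examined. The alternatives were the authors' processed values, no background correction, normexp from the signals alone with offset 50, median scaling, no detection filter, a stricter filter (detection p under 0.01 on every array of at least 1 group), eBayes with trend and robust settings, array weights, each tumour left out in turn, only the groups compared, thresholds of 2-fold and of an adjusted p of 0.01, all kept probes, other set tests, and other genes or measures for the similarity tests. Alternatives added after the data were seen were the mean raw intensity of an array as a covariate, leaving out together the 2 tumours that clustered alone, exact permutation of list scores, and unscaled distances. Slide as a block was not run because the tables used here carry no slide identifiers. The number of arrays limits the precision of every value.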

Results

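The series compares primary MMTV-Neu mammary tumours with secondary tumours grown from transplanted lin- cells or from a single TIC, and asks which genes differ and how alike the tumours are. Between 12513 and 13163 probes were detected per array, 48.7% to 51.2% of all probes. Mean raw intensity was 961 ± 52.4 (mean ± SD) in the 9 single TIC tumours and 882 ± 57.1 in the 5 primary tumours, a difference of 79.0 (two-sided exact permutation p = 0.0225). The percent of probes detected was 50.2 and 49.7 (exact permutation p = 0.179). In the 2 lin- tumours mean raw intensity was 961 ± 85.8 (exact permutation p = 0.190 against primary tumours).

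Some interferon-stimulated genes were among the largest rises in single TIC against primary tumours. Isg15, which encodes a ubiquitin-like protein induced by interferon, rose by 2.12 on the log2 scale (SE 0.35, adjusted p = 0.00648; 10.68 ± 0.69 in 9 single TIC and 8.57 ± 0.65 in 5 primary tumours, 4.33-fold). Bst2, which encodes tetherin, rose by 2.06 (SE 0.35, adjusted p = 0.00698), and Ifi27l2a by 2.37 (SE 0.46, adjusted p = 0.00999). Ly6c1, a surface antigen of myeloid and endothelial cells, rose by 1.73 (SE 0.26, adjusted p = 0.00473). The probes of Ifi27l2a and Ly6c1 may not separate these genes from near-identical family members. As the naming rule requires, all 9 single TIC tumours lay above the primary mean for each of these 4 genes. The calls of these 4 genes held without any 1 tumour.

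Another 5 of the 12 largest rises were Ccl8, Ccl7, Pf4, Cxcl9 and Rarres2. Ccl8, a monocyte attractant, rose by 2.95 (SE 0.70, adjusted p = 0.0233; 9.58 ± 1.33 against 6.63 ± 1.62, 7.74-fold) and was detected on 3 of 5 primary arrays. Ccl7, of the same family, rose by 1.55 (SE 0.37, adjusted p = 0.0233) and Pf4, a platelet and macrophage chemokine, by 1.49 (SE 0.33, adjusted p = 0.0187), each detected on 3 of 5 primary arrays. Cxcl9, induced by interferon gamma, rose by 2.29 (SE 0.59, adjusted p = 0.0331; detected on 4 of 5 primary arrays), and Rarres2, which encodes chemerin, by 1.85 (SE 0.46, adjusted p = 0.0279; 3 of 5). All 9 single TIC tumours were above the primary mean for all 5 genes, as the naming rule requires. Without primary 5 the adjusted p was 0.0690 for Ccl8, 0.0690 for Ccl7, 0.0526 for Pf4, 0.0945 for Cxcl9 and 0.0826 for Rarres2. Rarres2 also missed the threshold without primary 2 (0.0546), and Cxcl9 without primary 1 (0.0658), primary 2 (0.0503), primary 3 (0.0608) or single TIC 2 (0.0531).

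The remaining 3 of the 12 largest rises were Apof, an apolipoprotein gene (1.91, SE 0.51, adjusted p = 0.0388), Pik3r3, a regulatory subunit of PI3-kinase (1.84, SE 0.47, adjusted p = 0.0328), and Slc2a6, a hexose transporter (1.74, SE 0.38, adjusted p = 0.0166). All 9 single TIC tumours were above the primary mean for each, again by the naming rule. Slc2a6 missed the threshold without primary 3 (0.0533). Pik3r3 missed it without primary 1, 2, 3 or 5 or single TIC 7 or 8 (0.0503 to 0.0894), and Apof without the same 6 tumours or single TIC 2 or 4 (0.0501 to 0.0987).

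**Figure D1:**
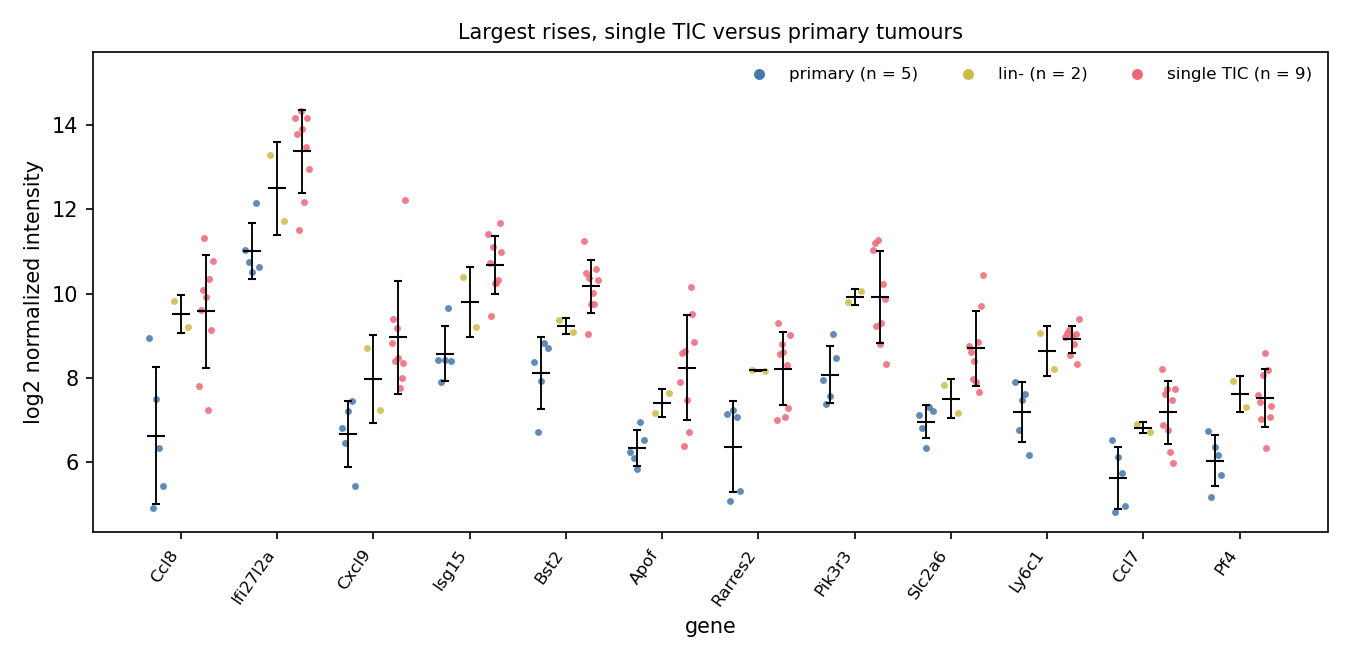
Log2 normalized intensity (vertical axis) of the 12 genes with the largest rises in single TIC against primary tumours (horizontal axis), 1 point per tumour, for 5 primary, 2 lin- and 9 single TIC tumours; black bars are mean ± SD. Every single TIC tumour lies above the primary mean of each gene, as the naming rule requires. Ccl8 and Cxcl9 have the widest spread among single TIC tumours (SD 1.33 for each).

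Among the largest falls were a pair of core circadian clock genes. Arntl, which encodes the clock activator BMAL1, fell by 1.42 (SE 0.19, adjusted p = 0.00319; 7.64 ± 0.38 against 9.06 ± 0.29, 2.68-fold). By the naming rule, all 9 single TIC tumours were below its primary mean. Npas2, whose protein pairs with BMAL1, was detected on 0 of 9 single TIC and 3 of 5 primary arrays and was at least 1.35-fold lower (adjusted p = 0.00780). Other clock genes were then looked up, chosen after their values were seen. Per1 fell by 1.02 (SE 0.16, adjusted p = 0.00644), while Per2 rose by 0.76 (SE 0.15, adjusted p = 0.0108), Dbp by 1.08 (SE 0.28, adjusted p = 0.0342) and Tef by 0.77 (SE 0.18, adjusted p = 0.0249). Of 18 clock genes measured, 3 rose, 3 fell and 12 did not pass. Tef missed the threshold without primary 5 (0.0694), and Dbp without primary 1, 2, 3 or 5 or single TIC 5 or 7 (0.0510 to 0.0912).

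The other large falls included transporter, steroid and secretory genes. Each was lower in all 9 single TIC tumours than the primary mean, as the naming rule requires. Slc15a2, a peptide transporter, fell by 1.35 (SE 0.27, adjusted p = 0.0117), Ovgp1, an oviductal glycoprotein gene, by 1.31 (SE 0.24, adjusted p = 0.00858; detected on 7 of 9 single TIC arrays), and Hsd3b2, a steroid dehydrogenase gene whose probe may also read close paralogs, by 1.22 (SE 0.27, adjusted p = 0.0179). These 3 calls held without any 1 tumour. Cyp17a1, a steroid hydroxylase, fell from 7.72 to 6.23 (adjusted p = 0.0190; 7 of 9 detected), Ccdc114, a ciliary gene, by 1.73 (adjusted p = 0.0233; 7 of 9), and Pisd-ps2, a transcribed pseudogene with near-identical relatives, by 1.90 (adjusted p = 0.0265). Without primary 1 their adjusted p was 0.0509, 0.0658 and 0.0511. Cyp17a1 was also lost without primary 5 (0.0588), Ccdc114 without primary 3 (0.0608), and Pisd-ps2 without primary 3 (0.0584) or primary 5 (0.0781).

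The last 4 of the 12 falls were Traf1, a TNF-receptor adaptor (fell by 1.47, adjusted p = 0.0363), Luzp2 (by 1.30, adjusted p = 0.0416; detected on 8 of 9 single TIC arrays), Mall (by 1.26, adjusted p = 0.0394; 5 of 9) and Lama1, a laminin chain (by 1.17, adjusted p = 0.0372), again with all 9 below the primary mean by the naming rule. Each was lost without primary 1, 3 or 5 (0.0640 to 0.116). Each was also lost without single TIC 7 or 8 (0.0550 to 0.0669). Traf1, Luzp2 and Mall missed the threshold without single TIC 2 (0.0531 to 0.0643), and Luzp2, Mall and Lama1 without single TIC 5 (0.0563 to 0.0613). Further losses were Mall without single TIC 1 (0.0596) or 4 (0.0570), Lama1 without primary 2 (0.0578), and Luzp2 without lin- 1 (0.0531) or lin- 2 (0.0528).

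**Figure D2:**
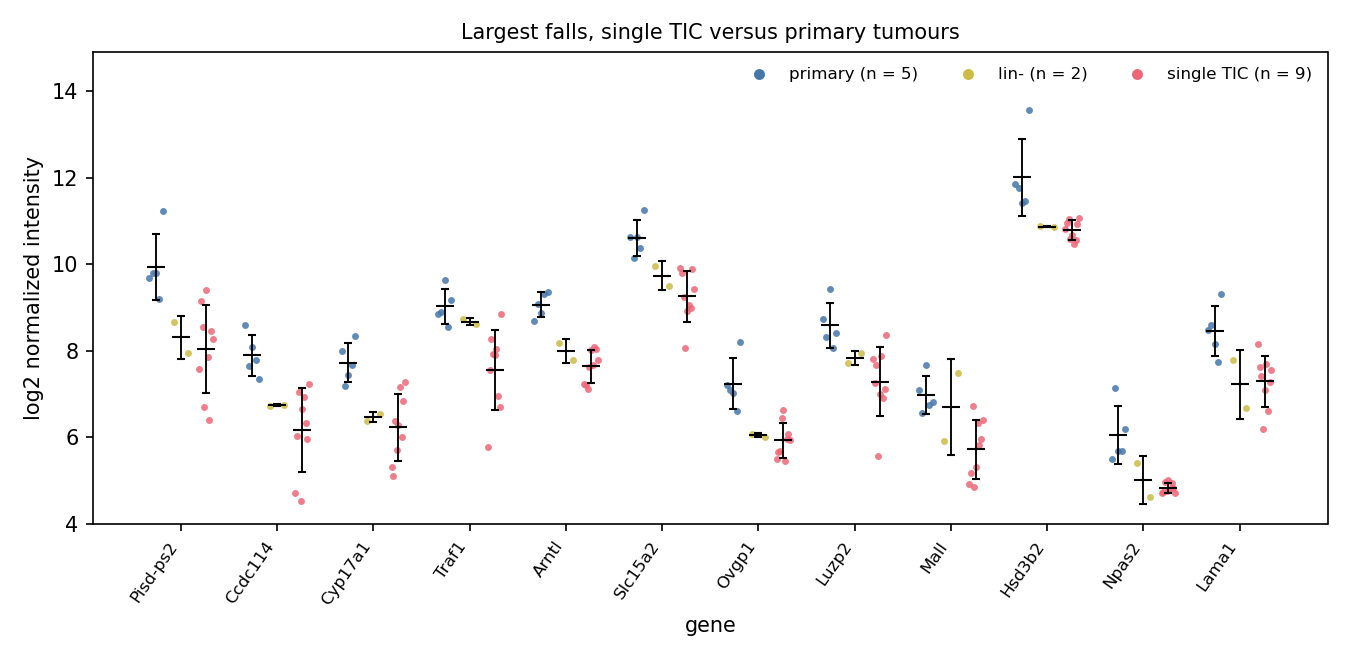
Log2 normalized intensity (vertical axis) of the 12 genes with the largest falls in single TIC against primary tumours (horizontal axis), 1 point per tumour, for 5 primary, 2 lin- and 9 single TIC tumours; black bars are mean ± SD. Every single TIC tumour lies below the primary mean of each gene, as the naming rule requires.

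In all, limma called 620 of 9903 genes between single TIC and primary tumours, 211 higher (34.0%) and 409 lower (66.0%). Of these, 64 changed at least 2-fold, 39 up and 25 down. At an unadjusted p under 0.05 there were 2507 genes, against 495 by chance. The smallest adjusted p, 0.00121, belonged to Pfdn2, a prefoldin subunit gene chosen after the values were seen, which rose by 0.84 (SE 0.10). The count was 294 without primary 1, 260 without primary 3 and 278 without primary 5. With mean raw intensity as a covariate it was 18, with 12 higher and 6 lower, of which 17 were among the 620. Of the 41 called genes named for this comparison, Arntl, Ly6c1, Pdia3 and Pfdn2 stayed called with that covariate.

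Camera called 9 of the 25 gene lists higher in single TIC than in primary tumours and 0 lower. With an estimated correlation it called 0 (smallest adjusted p = 0.519), and exact permutation of list scores gave 0 (smallest adjusted p = 0.0624). Fry called 3, the epithelial-mesenchymal transition and oxidative phosphorylation lists up and the ErbB list down (adjusted p = 0.0442 each). The ErbB list was tested without Erbb2, which had no named probe. Its test for change in either direction (PValue.Mixed) also does not compare a list with other genes.

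All 28 measured interferon response genes were higher in single TIC tumours (median log2 change 0.91, camera adjusted p = 7.26e-10; adjusted p = 0.589 with an estimated correlation). Of these, 5 rose, 0 fell and 23 did not pass, and 9 rose adjusted over the list alone. Besides Bst2, Cxcl9 and Isg15, those that rose were the immunoproteasome genes Psmb8 (1.44, SE 0.27, adjusted p = 0.00866) and Psmb9 (1.18, SE 0.29, adjusted p = 0.0271), named after the values were seen. Psmb9 was lost without primary 3 (0.0821) or primary 5 (0.0770), and Cxcl9 without the 5 tumours given above (0.0503 to 0.0945). Ifit3 did not pass (1.70, SE 0.57, adjusted p = 0.0825), but did without primary 4 (0.0480).

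Lists for stromal cells were also higher. Of 25 fibroblast and matrix genes 21 were higher (median 1.19, camera adjusted p = 1.63e-05; adjusted p = 0.589 with an estimated correlation), yet 0 rose over all genes tested and 0 adjusted over the list alone. Dcn, a matrix proteoglycan gene, was higher by 2.80 (SE 1.15, adjusted p = 0.141) and Bgn, its relative, by 2.15 (SE 0.75, adjusted p = 0.0947). Dcn passed without single TIC 6 (0.0398) and Bgn without primary 1 (0.0374). Of 17 endothelial genes 15 were higher (median 0.86, camera adjusted p = 1.64e-05; adjusted p = 0.589 with an estimated correlation), with 1 called over all genes and 8 adjusted over the list alone. The called gene was Ramp2, an adrenomedullin receptor partner (1.33, SE 0.32, adjusted p = 0.0233; 0.0652 without primary 5). Pecam1, an endothelial junction marker, did not pass (0.77, SE 0.29, adjusted p = 0.113).

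Camera also called the macrophage and MHC class II lists, though no gene of either passed. Of 18 macrophage genes 16 were higher (median 0.50, camera adjusted p = 0.000157; adjusted p = 0.589 with an estimated correlation), with 0 called and 3 adjusted over the list alone. Laptm5, a lysosomal protein of blood cells, was higher by 0.82 (SE 0.27, adjusted p = 0.0787; 0.00592 without primary 2). Of 12 MHC class II genes 11 were higher (median 0.32, camera adjusted p = 0.00798; adjusted p = 0.619 with an estimated correlation) and 0 passed, also adjusted over the list alone. H2-Ab1 was higher by 1.39 (SE 0.55, adjusted p = 0.131). Without primary 5 the MHC class II list had a camera adjusted p of 0.0594.

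Of 16 epithelial-mesenchymal transition genes 14 were higher (median 0.38, camera adjusted p = 0.000288; adjusted p = 0.519 with an estimated correlation). Lgals1, which encodes galectin-1, rose by 0.95 (SE 0.18, adjusted p = 0.00981) and Tgfbi, a matrix gene induced by TGF-beta, by 1.21 (SE 0.30, adjusted p = 0.0274). Adjusted over the list alone, 6 rose and 1 fell. Tgfbi was lost without primary 1 (0.0507), primary 3 (0.0583), primary 4 (0.0537) or primary 5 (0.0808). Of 19 unfolded protein response genes 15 were higher (median 0.23, camera adjusted p = 0.00213; adjusted p = 0.589 with an estimated correlation). The oxidoreductase gene Pdia3 rose by 1.02 (SE 0.14, adjusted p = 0.00390) and Creld2 by 0.82 (SE 0.17, adjusted p = 0.0151), and the same number, 2, passed adjusted over the list alone.

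All 28 proliferation genes had a higher mean (median 0.29, camera adjusted p = 0.000308, adjusted p = 0.723 with an estimated correlation). Of these, 0 passed over all genes or adjusted over the list alone. The list score was -0.72 in primary 2 and -0.89 in primary 5. It was 0.34, 0.12 and 0.21 in primary 1, 3 and 4, within the single TIC range of -0.40 to 0.69. Pcna, the replication clamp, was higher by 0.61 (SE 0.18, adjusted p = 0.0519) and passed without primary 4 (0.0189) or single TIC 9 (0.0354). Tpx2, a spindle gene, was higher by 0.85 (SE 0.35, adjusted p = 0.142). The proliferation list, single TIC versus primary, was lost without primary 5 (0.0857), with array weights (0.0606) and without the 2 tumours that clustered alone (0.0877). Of 33 oxidative phosphorylation genes 30 were higher (median 0.11, camera adjusted p = 0.000158; adjusted p = 0.519 with an estimated correlation). Atp5o, an ATP synthase subunit, rose by 0.53 (SE 0.12, adjusted p = 0.0166; 0.0533 without primary 3), the 1 gene also passing adjusted over the list alone.

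**Figure D3:**
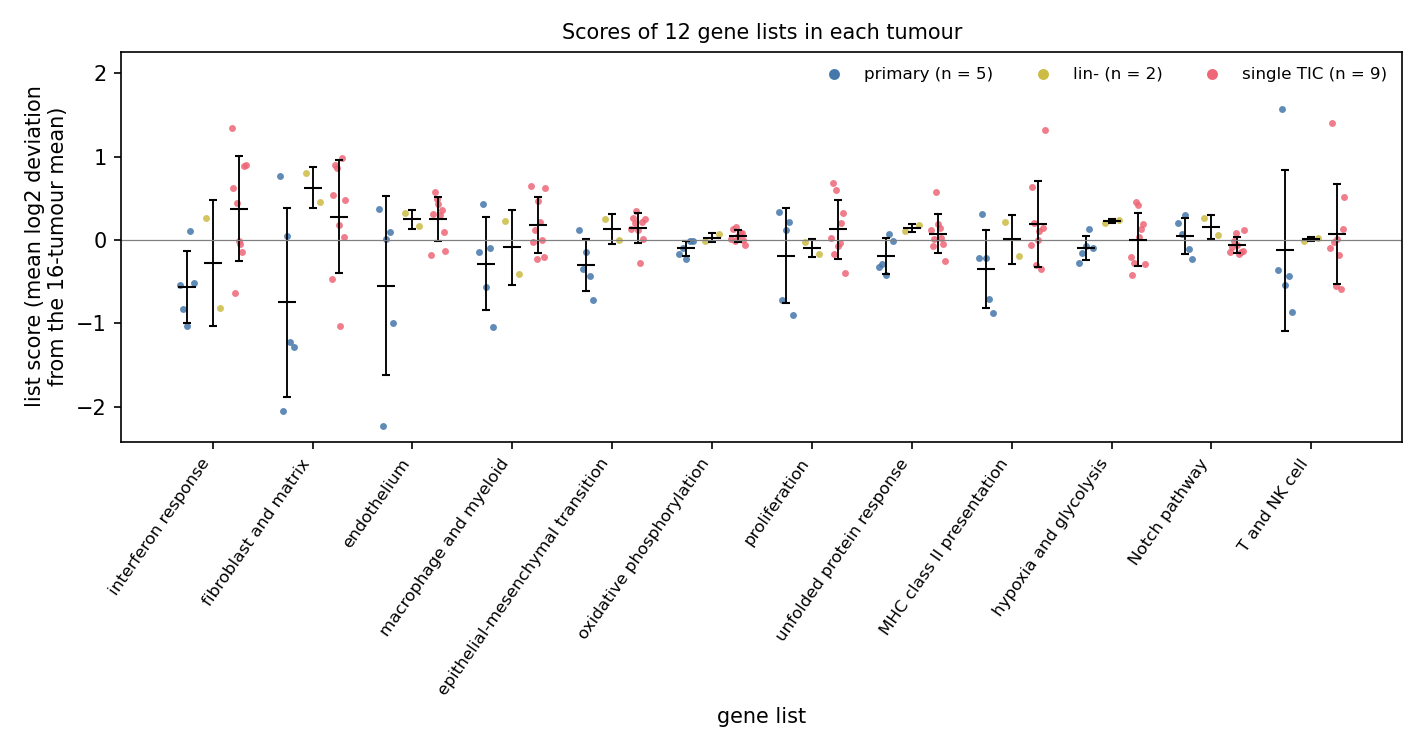
Score of 12 gene lists (horizontal axis) in each tumour, as the mean log2 deviation of list genes from their 16-tumour mean (vertical axis), for 5 primary, 2 lin- and 9 single TIC tumours; points are tumours and black bars mean ± SD. Primary 2 has the lowest fibroblast (-2.05) and endothelium (-2.23) scores and the highest T and NK cell score (1.57).

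The other 16 tested lists were not called between single TIC and primary tumours. Among epithelial lists, luminal genes gave a camera adjusted p of 0.907 (12 of 17 lower, while the test pointed up), and Cldn7, a tight-junction gene, rose by 0.54 (SE 0.12, adjusted p = 0.0179; 0.0511 without primary 1). The basal list gave 0.696, with Acta2, smooth-muscle actin, higher by 1.96 without passing (adjusted p = 0.126). The milk list gave 0.514 with 13 of 18 genes lower. Lalba, the milk protein alpha-lactalbumin, named after the values were seen, fell by 0.71 (SE 0.17, adjusted p = 0.0217; 0.0530 without primary 1 and 0.0582 without primary 5), and 3 fell adjusted over the list alone. Camera adjusted p was 0.372 for T and NK cells, 0.869 for neutrophils (median 0.05, mean -0.01), 0.696 for B and plasma cells, 0.0955 for adipocytes, 0.907 for skeletal muscle and 0.696 for erythrocytes. The T and NK list passed without primary 2 (0.000529) and the adipocyte list without single TIC 6 (0.0306).

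Pathway lists were not called either. Erbb2 had no named probe and is not among the measured ErbB genes. Camera adjusted p was 0.0772 for the ErbB list (11 of 14 genes lower; 0.0395 without primary 1 and 0.0411 without single TIC 7), 0.431 for the Notch list, 0.431 for hypoxia and glycolysis, 0.869 for immediate early and heat shock genes and 0.907 for ribosomal proteins (median and mean negative, while the test pointed up). The Wnt list gave 0.907, again with median and mean negative and the test up. In it the transcription factor gene Tcf7l2 fell by 0.59 (SE 0.15, adjusted p = 0.0335) but not without primary 1, 2, 3 or 5 or single TIC 2 (0.0531 to 0.0857). The stem and progenitor list gave 0.861 (median -0.03, mean 0.01). In it Inhbb, an activin subunit, fell by 0.81 (SE 0.22, adjusted p = 0.0432; 8 of 9 below the primary mean), a call that leaving out any of 12 tumours ended (0.0539 to 0.0987): primary 1, 2, 3 or 5, lin- 1 or 2, or single TIC 1, 2, 4, 5, 7 or 8. The surface markers Cd24a (-0.01, SE 0.28, adjusted p = 0.988) and Itga6 (0.06, SE 0.15, adjusted p = 0.839) did not pass, nor did Ptprc, the leukocyte marker CD45, detected on 1 of 9 and 1 of 5 arrays. Of the untested skin keratinocyte list, Krt10, Sprr1a, Lor and Sbsn were measured and did not pass.

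No single gene passed between lin- and primary tumours. Limma called 0 genes, with 975 at an unadjusted p under 0.05. Pfdn2, chosen after the values were seen, had the smallest adjusted p, 0.0664 (0.96, SE 0.15). Dcn was higher by 3.73 (SE 1.72, adjusted p = 0.499), Ccl8 by 2.89 (SE 1.05, adjusted p = 0.394), Isg15 by 1.24 (SE 0.53, adjusted p = 0.462) and Pdia3 by 1.04 (SE 0.21, adjusted p = 0.136), and Arntl was lower (-1.08, SE 0.28, adjusted p = 0.303). The gene count was 4 without primary 2, 7 without primary 4 and 1 without primary 5, with Pfdn2 passing each time (0.0478, 0.0405 and 0.0167).

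Camera called 6 lists higher in lin- than in primary tumours and 0 lower, against 0 with an estimated correlation and 0 by fry. Exact permutation of scores gave 0 as well (smallest adjusted p = 0.397). These tumours allow 21 splits, so few that this permutation could hardly call a list after adjustment, and its 0 decides nothing. The 6 lists called by camera included the fibroblast list (camera adjusted p = 1.86e-08; adjusted p = 0.624 with an estimated correlation), endothelium (5.42e-05; adjusted p = 0.739 with an estimated correlation) and the unfolded protein response (0.000496; adjusted p = 0.624 with an estimated correlation), where Pdia3 was the 1 gene passing adjusted over the list alone. The others were epithelial-mesenchymal transition (0.000903; adjusted p = 0.624 with an estimated correlation), oxidative phosphorylation (0.00242; adjusted p = 0.624 with an estimated correlation) and hypoxia and glycolysis (0.00593; adjusted p = 0.739 with an estimated correlation). In the last, Adm, the adrenomedullin gene, was higher by 1.40 (SE 0.65, adjusted p = 0.502). Without lin- 1 the transition list lost its call, and without lin- 2 the oxidative phosphorylation list did. These 2 fits leave 1 lin- tumour, so only scores are given for them. The interferon score was 0.26 in lin- 1 and -0.81 in lin- 2, so the 2 lin- tumours differed. The interferon list (camera adjusted p = 0.0593) passed without primary 4 (0.00431), primary 5 (0.0464), single TIC 3 (0.0402) or single TIC 9 (0.0392). The macrophage (0.00278), T and NK (0.0128) and MHC class II (0.0116) lists passed without primary 2. The macrophage score was 0.23 in lin- 1 and -0.41 in lin- 2, and the B and plasma cell score -0.21 and 0.91.

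Between the secondary groups limma called 0 genes, with 167 at an unadjusted p under 0.05, below the 495 that chance gives. The smallest adjusted p was 0.270 for Per1, chosen after the values were seen, whose mean was 9.29 in single TIC, 10.62 in lin- and 10.31 in primary tumours (-1.34 against lin-, SE 0.23). It was called, as the 1 gene, without single TIC 1 (0.0347). Ifit3, an interferon-induced gene, was higher in single TIC tumours by 1.57 (SE 0.80) and Vegfa, the angiogenic factor, lower (-0.71, SE 0.48), without passing.

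Camera called 3 lists higher in single TIC than in lin- tumours: interferon response (27 of 28 genes, median 0.65, camera adjusted p = 2.83e-10; adjusted p = 0.968 with an estimated correlation), proliferation (0.00109; adjusted p = 0.968 with an estimated correlation) and macrophages (0.00696; adjusted p = 0.968 with an estimated correlation). It called 2 lower: hypoxia and glycolysis (0.00905; adjusted p = 0.968 with an estimated correlation) and Notch (0.00905; adjusted p = 0.480 with an estimated correlation), where Dll1, a Notch ligand gene, was lower (-0.88, SE 0.54) without passing. Fry and exact permutation each called 0 lists, but the 55 possible splits left exact permutation little room to call a list after adjustment. Without lin- 2, the interferon, proliferation, hypoxia and macrophage lists lost their calls, and the macrophage list turned down. Without lin- 1, hypoxia and Notch were lost. These 2 fits leave 1 lin- tumour, so no p-value is given for them. The fibroblast list (0.0619, down) passed without primary 1 or 2 or single TIC 2, 3, 4, 7 or 9 (at most 0.0473). The B and plasma cell list passed, down, without single TIC 2 (0.00752).

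With all 11 secondary tumours set against the 5 primary tumours, 9 of which are the single TIC tumours above, 12 genes are named by the rule. Isg15 rose by 1.96 (SE 0.36, adjusted p = 0.00592), Ccl8 by 2.94 (SE 0.66, adjusted p = 0.0145), Ifi27l2a by 2.21 (adjusted p = 0.0110), Bst2 by 1.89 (adjusted p = 0.00729), Cxcl9 by 2.11 (adjusted p = 0.0353) and Rarres2 by 1.85 (adjusted p = 0.0173). Arntl fell by 1.36 (SE 0.18, adjusted p = 0.00164), Ovgp1 by 1.28 (adjusted p = 0.00470), Slc15a2 by 1.27 (adjusted p = 0.0117), Cyp17a1 by 1.45 (adjusted p = 0.0136), Pisd-ps2 by 1.85 (adjusted p = 0.0182) and Ccdc114 by 1.63 (adjusted p = 0.0213). All 11 secondary tumours lay on the same side of the primary mean for each, as that rule requires. Limma called 758 genes, 250 higher (33.0%) and 508 lower (67.0%), and 585 were also among the 620. At least 2-fold changes were found for 70 of them, 47 higher and 23 lower. The count was 431 without primary 1, 386 without primary 3 and 377 without primary 5. With mean raw intensity as a covariate it was 32, with 17 higher and 15 lower. Of the 12 named calls, 8 were lost with the secondary groups weighted equally, which left Isg15, Bst2, Arntl and Ovgp1, and 11 with mean raw intensity as a covariate, which left Arntl. Cxcl9 was lost without primary 1, 2, 3 or 5 or single TIC 2 (0.0532 to 0.104), Ccdc114 without primary 1 (0.0648) or 3 (0.0584), and Rarres2 (0.0610) and Pisd-ps2 (0.0645) without primary 5.

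Across the 9903 genes, changes of lin- and of single TIC tumours against the same primaries correlated at r = 0.807, where genes are not independent replicates. Simulated groups with no difference, which share their primaries in the same way, gave a mean r of 0.425 (-0.0291 to 0.696 in 100 simulations). With the primaries split between the comparisons, which then share no tumour, the mean r was 0.473 (0.360 to 0.641). That value rests on fewer primaries per comparison and does not compare directly with the simulated one. The covariance of the changes was 0.113 with shared primaries, 0.0340 on average in the simulations and 0.0813 on average with split primaries.

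**Figure D4:**
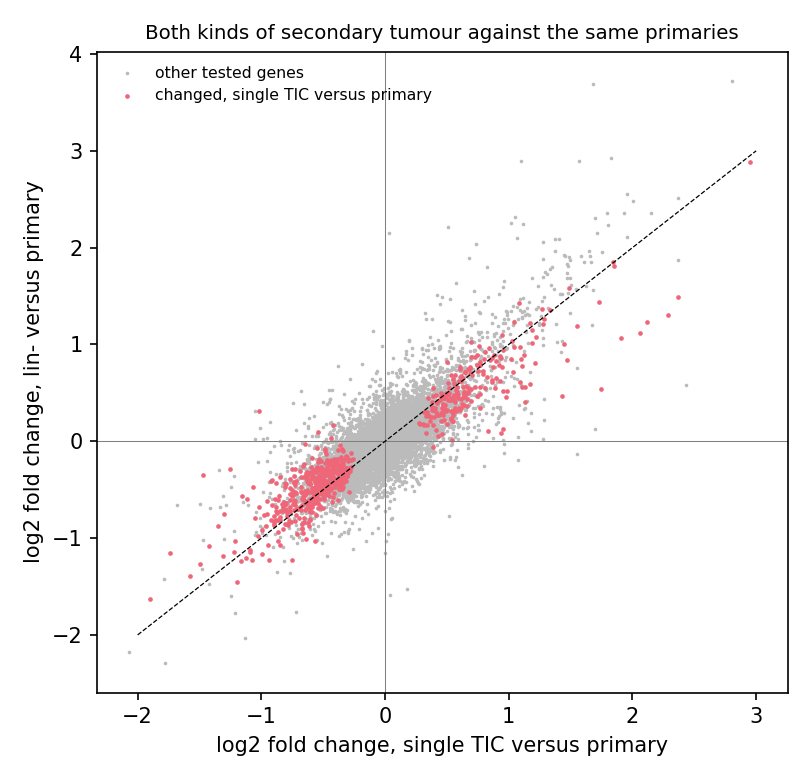
Log2 fold change of each of 9903 genes in single TIC (horizontal axis) and lin- tumours (vertical axis) against the same 5 primary tumours; the 620 genes changed in single TIC tumours are coloured and the dashed line marks equal values. The correlation over all genes is 0.807.

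Whole profiles grouped only in part by kind of tumour. Mean r was 0.973 within primary and 0.972 within single TIC tumours, and 0.965 between them, a within-minus-between difference of 0.00694 (two-sided exact permutation p = 0.0030). The exact permutation p was 0.0895 without primary 5 and 0.123 over the 1000 most variable genes. Mean distance within groups was 56.3 for single TIC and 55.9 for primary tumours. The planned scaled statistic was -2.70 (exact permutation p = 0.662), and without scaling by group size 0.481 (exact permutation p = 0.933). Single TIC 4 clustered alone first and primary 2 next, and the adjusted Rand index against the 3 groups was -0.0609 at 2 clusters and -0.0192 at 3, where the other cluster held 4 primary, 2 lin- and 8 single TIC tumours. Complete linkage gave 0.325 at 3 clusters. The first cluster held all 5 primary tumours and single TIC 6, the next both lin- and 4 single TIC tumours, and the last 4 single TIC tumours. The nearest other tumour was of the same group for 4 of 5 primary, 6 of 9 single TIC and 0 of 2 lin- tumours. Lin- 1 lay nearest to single TIC 5 (r = 0.985) and lin- 2 to single TIC 8 (r = 0.983).

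**Figure D5:**
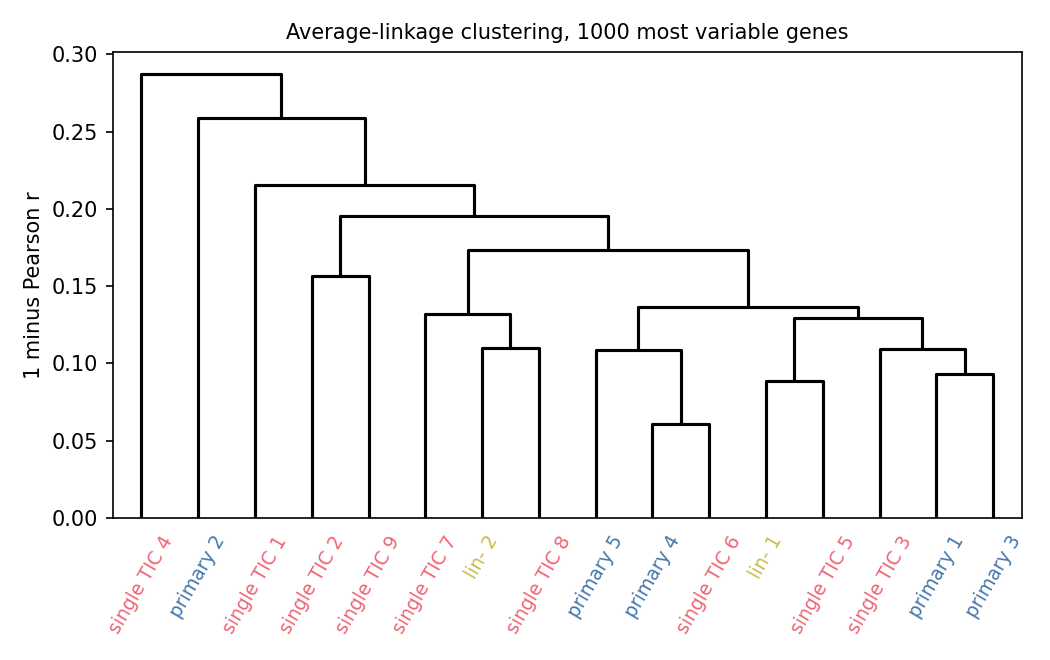
Average-linkage tree of the 16 tumours over the 1000 most variable genes, with the height of each join as 1 minus Pearson r (vertical axis) and tumour names coloured by group (horizontal axis). Single TIC 4 and primary 2 join last.

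The list scores of the tumours that clustered alone, and of others with low scores, were as follows. Single TIC 4 had milk and luminal scores of -1.80 and -0.41. Primary 2 scored 1.57 for T and NK cell genes. By Dixon's test these 3 scores were far from their group. Primary 2 also scored -2.05 for fibroblast and -2.23 for endothelial genes, which did not exceed the critical value. Nor did the scores of primary 5 for proliferation genes (-0.89) or of single TIC 6 for fibroblast genes (-1.03). Primary 5 scored -1.29 for fibroblast and -1.04 for macrophage genes. These scores were not tested, because the test takes 1 extreme tumour per group.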

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

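In this part, the search for tumours far from their group and for unnamed probes was planned; chosen after the result was seen were the test on the size of the falls, the share among the genes with the smallest p, the demand that genes be detected on every array, and the rule that scores made only of called genes exclude nothing. Chance alone puts a tumour far from its group in about 1 in 20 groups. In 104 measures tested in each group, a highest or lowest tumour had a gap to the next above Dixon's 95% critical value 3 times among primary and 8 times among single TIC tumours, against 5.2 by chance for each. Single TIC 4 was far below the other single TIC tumours for the luminal score (-0.41) and the milk score (-1.80). Primary 2 was high for T and NK cell genes (1.57) and primary 1 for skeletal muscle genes (1.44). Single TIC 2 was high for B and plasma cell genes (1.59) and for Ptprc (5.61), and single TIC 1 for muscle genes (0.67). Single TIC 9 stood apart for Cxcl9 (12.23) and Per2 (10.78), primary 5 for Hsd3b2 (13.56) and single TIC 6 for Dcn (5.15). Outside the named genes, 57 of 839 kept probes without a gene name differed between single TIC and primary tumours, 16 higher and 41 lower. That share is close to the one among tested genes, 620 of 9903, with 211 higher and 409 lower.

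Some clock genes differed between single TIC and primary tumours, and the clock score (mean of Dbp, Tef and Per2 minus mean of Arntl, Npas2 and Per1, the 6 called of 18) differed by 2.09. Each gene stands on the side of the score given by the direction of its change, so Per1 and Per2 are on opposite sides. With the fibroblast score as a covariate the difference was 1.73 (95% interval 1.10 to 2.35), above the 1.04 set beforehand as arguing against the share of stromal cells. Without Npas2, which was not detected on every array, it was 1.78 (1.26 to 2.31) against 1.05. A score made only of called genes is biased away from 0, so the share of stromal cells stays open. Among clock genes that did not pass, Ciart was higher by 0.86 and Nfil3 lower by 0.76. Nr1d1 (-0.21), Nr1d2 (0.22), Per3 (0.20) and Bhlhe40 (-0.05) changed less. Collection at another time of day was neither shown nor excluded as the cause. The mean of Usp2 and Wee1, which follow Dbp and Per2 over the day, differed by 0.0736 (-0.18 to 0.32, exact permutation p = 0.521). Its upper bound was below the 0.435 set beforehand as arguing against that cause. That value was not used to exclude it, because Wee1 was detected on 3 of 14 arrays and Usp2 alone gave 0.22 (-0.29 to 0.73), and a difference between transplanted and primary tumours was not tested apart from it.

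The interferon list score was higher in single TIC tumours by 0.93 (camera adjusted p = 0.589 with an estimated correlation; exact permutation adjusted p = 0.133), and no tested cause was excluded. The difference was 0.92 (0.19 to 1.66) with the T and NK score as a covariate, 0.83 (0.00080 to 1.66) with the macrophage score and 0.79 (-0.11 to 1.69) with array brightness. Each interval reaches below the 0.47 set beforehand, but the interval without a covariate did so already (0.24 to 1.63). The bound could therefore hardly be met with any covariate. It neither excludes a share of immune cells or array brightness nor shows a part for them.

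More of the called genes were lower than higher, but not of those changed at least 2-fold (39 higher, 25 lower). The lower share was 66.0%, and 59.5% with median scaling and 56.5% without primary 1. Whether array brightness had a part in it could not be decided. With mean raw intensity as a covariate, 33.3% of the 18 genes called were lower (95% interval 13.3 to 59.0), which met the value set beforehand for brightness as the cause, under 55%. Without the covariate the 18 genes with the smallest p were already 50% lower, so that share does not measure the covariate's effect. The size of the 409 falls was 0.56 (0.38 to 0.73) with the covariate and 0.60 without, which excludes nothing either, because the genes were chosen for being lower. Their median SE went from 0.128 to 0.153.

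Other splits of the tumours gave smaller gene counts. For single TIC against primary tumours, 1 of 100 splits (of 2002), the real one, gave 620 genes or more, and the highest other gave 9. For all secondary tumours 1 of 100 (of 4368) gave 758 or more, and the highest other gave 369. A chance division of these tumours was therefore excluded for both, as far as 100 splits can tell and if the tumours are independent. The labels do not say whether tumours shared donor animals or cell preparations, so a difference between donors was not excluded. For the 9 lists, 23 of 100 splits gave as many, the highest other giving 13 and the median other 7, so chance was not excluded. The lists called in comparisons with lin- tumours were not tested by splits.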

How the results depend on the processing

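Array brightness as a covariate, exact permutation of list scores, unscaled distances and leaving out together the 2 tumours that clustered alone were chosen after the data were seen. The 620 genes of single TIC against primary tumours became 64 at 2-fold or more, 105 at an adjusted p under 0.01, 948 with all kept probes as features and 18 with array brightness, and the 758 of all secondary tumours became 70, 126, 1176 and 32, and 226 with the secondary groups weighted equally. Leaving out 1 tumour gave 260 to 784 and 377 to 945. For lin- against primary tumours the count of 0 became 1 with the authors' values, without background correction, with normexp from the signals alone, without a filter, with the stricter filter and with trend and robust settings (Pfdn2 each time, adjusted p 0.0170 to 0.0422). It was 1 with only the groups compared (Dhh), 10 with array weights, 2 without the tumours that clustered alone (Ppp3r1 and Primpol) and 0 to 7 without 1 tumour. For single TIC against lin- tumours it was 1 with array weights (Per1) and 0 to 1 without 1 tumour. Lists called were 0 with an estimated correlation and 0 by exact permutation in the 3 comparisons, and 3, 0 and 0 by fry. In the comparisons with lin- tumours, exact permutation had too few splits (21 and 55) to be likely to call a list after adjustment. For single TIC against lin- tumours they were 1 to 7 without 1 tumour, and the macrophage list ranged from an adjusted p of 1.65e-05 without lin- 1 to 0.961 without lin- 2, where it turned down and the lone lin- tumour is assumed to vary like the other groups. The proliferation list, single TIC versus primary, was not called with array weights (adjusted p = 0.0606) or without the tumours that clustered alone (0.0877). The similarity difference was 0.0266 over the 1000 most variable genes (exact permutation p = 0.123) and 0.00507 to 0.00859 without 1 tumour. The Rand index of the clusters was 0.0642 with all genes, 0.325 with complete linkage, -0.123 with the authors' values, -0.123 without background correction and -0.0606 with normexp from the signals alone. Of 75 named genes for single TIC against primary tumours, 41 were called, and 38 of these 41 lost their call in some setting. Of the genes not called, 12 gained a call in some setting, and 0 of the 75 reversed. The other 25 kept their result in every setting, and most of them were never called. Slide as a block was not run, because no slide identifiers were in the tables used. No paired analysis was possible because the labels pair no tumours, and the cause of these shifts was not tested.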

Other observations

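Of 41 called genes named for single TIC against primary tumours, 16 kept their call without any 1 tumour: Isg15, Bst2, Ifi27l2a and Psmb8, which interferon induces, the clock genes Arntl, Npas2, Per1 and Per2, the endoplasmic reticulum genes Pdia3 and Creld2, and Ly6c1, Lgals1, Slc15a2, Ovgp1, Hsd3b2 and Pfdn2. These genes were named by rule or after their values were seen, and no test of groups was run on them. With array brightness as a covariate 4 of the 41 calls remained, Arntl, Ly6c1, Pdia3 and Pfdn2.

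Primary 2, primary 4 and primary 5 had the lowest fibroblast scores among primary tumours (-2.05, -1.23 and -1.29). Leaving out primary 5 ended the calls of the proliferation (0.0857) and MHC class II (0.0594) lists in single TIC against primary tumours, which were also lost with an estimated correlation (adjusted p = 0.723 and 0.619), with fry and with exact permutation of scores. The proliferation list was lost with array weights and without the 2 tumours that clustered alone as well. Per1 had a mean of 10.62 in lin-, 9.29 in single TIC and 10.31 in primary tumours, and its difference between the secondary groups did not pass (adjusted p = 0.270).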
